A study of Mus musculus with 6 samples.

How the data were processed

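Total RNA from mouse pancreatic cancer cell lines FC1199-OVA and FC1242-OVA was extracted on silica columns with DNase treatment, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. Both lines come from KPC mice on a C57Bl/6 background and had been infected with a lentivirus encoding ovalbumin and GFP by centrifugation of the cells with the virus. The labelling protocol names a human array, but the probe set identifiers of the deposited values are those of a mouse array, and the values were read as mouse. The authors deposited 1 table of log2 expression values, 1 per probe set and array, and no scanner files were used here. The processing tools named in the submitters' processing notes are RMA and limma, without versions. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set. That the values are on the log2 scale and on one scale over the arrays was read from the values, which run from 1.54 to 15.2 with array medians of 5.21 to 5.25. How RMA was parameterised, and any genome build behind the probe annotation, are not given in the sources used here. No detection calls were used, so a dim value cannot be told from an absent transcript, and differences that reach into dim values are compressed. For arrays, their number limits the precision, here 3 per line.

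The table held 38077 probe sets and 0 missing values, and each column belonged to 1 sample. Probe sets were named with the array annotation supplied for the platform, whose Entrez identifiers were looked up in a RefSeq gene table of assembly GRCm38.p6. This changed 0 symbols, and 54 probe sets had an identifier that was not in that table. After 13 control probe sets were left out, 34248 probe sets named 1 gene, 111 named several and 3705 named none. Only the first kind was used for named genes, which gave 17931 genes, 8821 of them with more than 1 probe set. Each gene was represented by its probe set with the highest mean over all 6 arrays. Of 2729 genes with at least 2 called probe sets, 148 had called probe sets of opposite sign. Of 84 called genes with several probe sets among those chosen by the naming rule or later, 0 had another probe set called in the other direction. In 17, no other probe set was called in the same direction, namely Kdm5d, Eif2s3y, Dhx58, Gbp7, Tnfrsf1b, Icosl, Nt5e, Plk2, Tgfbr3, Pfkfb3, Des, Prss2, H2-D1, Tapbp, Dbf4, Stat2 and Psmd7. The 3816 probe sets without a single gene were tested apart, and 727 were called, 126 of them with a 2-fold change.

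Samples were grouped by the line named in their titles. The comparison was FC1242-OVA minus FC1199-OVA over all 6 arrays, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 at default settings, without covariates and with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all 17931 genes, and a gene was called at an adjusted p under 0.05. A 2-fold change is an absolute log2 difference of at least 1. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for tables and for the order of genes. The labels give no batch, scan date or slide. The replicates are biological by the series design, which does not say how they were separated, so p-values measure the spread between these samples. The comparison, its alternatives, the naming rule and the 28 gene and marker lists were fixed before the data were examined.

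The lists were tested with camera at its preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over the 28 lists. The result of 1 list and the genes named only through it are not reported here. Camera with an estimated correlation and fry were run beside it. Between 4 and 38 genes per list were measured, for example 20 of the 25 listed for MHC class I presentation, and the other listed genes were not analysed here. Counts of called members are given over all genes and adjusted over the list alone.

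The named genes are Cldn18, the 10 genes with the largest difference in each direction and up to 4 called members of each list with the largest difference, 112 genes in all. Genes of the top 10 had to be called, to differ at least 2-fold, to have no overlap between the lines and to have a higher group above the median of all genes, 6.12, and symbols made of Gm or LOC and digits, or ending in Rik, were passed over. No such level was asked of list members. Among those named or drawn, Tap2, Dhx58, Gbp7, Irf7, Stat2, Il15, Cxcl10, Ccl5, Icosl, Tgfb2, Vtcn1, Cd274, Cldn4, Cldn7, Tspan33, Dsg2, Krt15, S100a14, Ccne2, Cdkn1c, Eno2, Uty, Des and Emcn were called although they lay below it in both lines. Other genes were chosen after their values were seen. These are B2m, H2-D1, Tapbp, Mki67, Top2a, Cdk1, Alcam, Cd274, Cd9, Cdh1, Krt8, Krt18, Vim, Gata6, Cxcl9, Cxcl10, Ccl5, Stat2, Hmgcs1, Cyp51, Xist, Ptprc and the other leukocyte transcripts of the closing section, Dcn, Tjp1 and Ocln, the further claudins drawn in the plot of claudin genes, the further members of the families in the closing section and the neighbours of Cdk6.

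The test was tried on simulated data with the means of the real genes, in which 50 genes each were changed by 0.5, 1, 2 or 4 on the log2 scale among 17931. It recovered 64%, 96%, 100% and 100% of them and called 8 unchanged genes. Camera called the 1 simulated list that had been moved and 0 of 19 others. The simulated genes were drawn independently, and far fewer were changed than were called in the real data. The trial therefore cannot show how often camera calls lists wrongly where members correlate, as estimated at 0.204 for proliferation and 0.164 for cholesterol synthesis. The alternatives were the replicate number as a block, the mean of all probe sets of a gene, every probe set on its own, a filter on dim genes (below the median of all genes in both lines), eBayes with trend and robust settings, array weights, quantile normalization, centring of each array on its median, limma's treat against a 2-fold change, an estimated correlation, fry, and leaving out each array in turn. An alternative for values not on a log scale did not apply.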

Results

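Gene expression was measured with Affymetrix arrays in a pair of mouse pancreatic cancer cell lines, FC1199-OVA and FC1242-OVA. Both lines were derived from KPC mice, a genetically engineered model of pancreatic cancer, and both carry the H-2b haplotype. Each line had been infected with a lentivirus that encodes ovalbumin, a model antigen for T cells, together with GFP. Each line was represented by 3 arrays, which the series design describes as biological replicates, and all 6 arrays entered the comparison. After the array's control probe sets were left out, 17931 genes were tested. The median log2 value per array lay between 5.21 and 5.25. Arrays of the same line correlated across genes with Pearson's r of 0.9963 to 0.9975, and arrays of different lines with r of 0.9702 to 0.9724, where genes are not independent replicates. The first principal component separated the lines and held 86.7% of the variance. Differences are given throughout as FC1242-OVA minus FC1199-OVA on the log2 scale, so a negative value is a gene higher in FC1199-OVA. Values per line are means ± SD (n = 3), and adjusted p-values of single genes are from limma.

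The title of the series is about claudin 18 on cancer cells and T cell infiltration, so the first question was how the lines differ in Cldn18, which encodes a tight junction protein of stomach and lung epithelium. Cldn18 had the largest difference of all 17931 genes when each was represented by its brightest probe set, and the second largest, after Sox2, with the mean of all probe sets of a gene (−7.45 against 8.05). The brighter of its 2 probe sets measured 12.36 ± 0.18 in FC1199-OVA and 3.71 ± 0.29 in FC1242-OVA (n = 3 each). The difference was −8.65 (SE 0.15, 95% confidence interval −9.01 to −8.3, adjusted p = 2.33e-08), which is 403-fold on the array's scale. The other probe set measured 9.95 ± 0.84 and 3.70 ± 0.16, a difference of −6.25 (SE 0.36, adjusted p = 1.01e-05 with every probe set tested on its own). Within each FC1199-OVA array, Cldn18 lay above 98.5% to 98.9% of all genes. In the FC1242-OVA arrays it lay above 17.5% to 24.3%, in the range of dim probe sets, where array values flatten and folds come out too small. No detection calls were used here, so whether any transcript was present in FC1242-OVA was not determined.

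**Figure D1:**
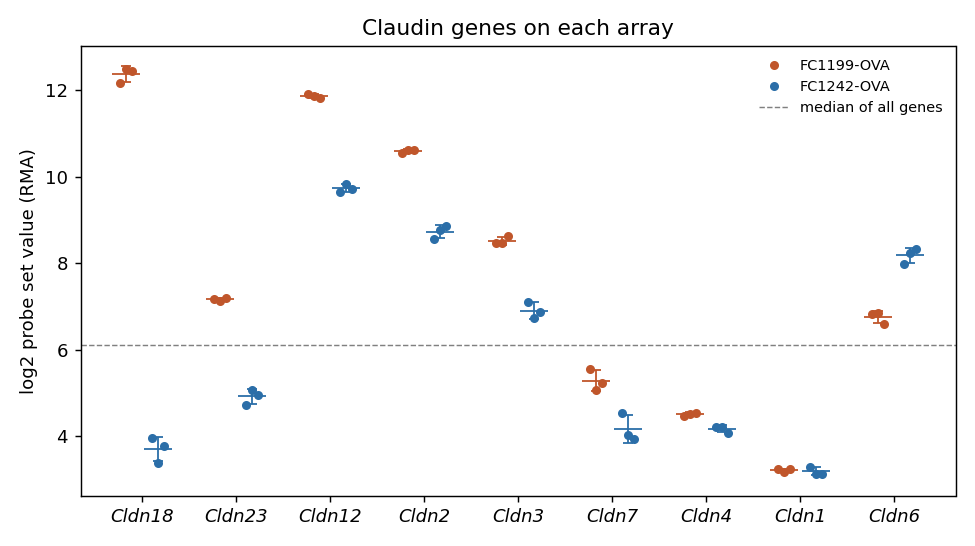
Log2 probe set values (vertical axis) of 9 claudin genes (horizontal axis) on the 3 arrays of each line, with points for arrays, horizontal marks for means and bars for SD; the dashed line is the median of all genes, 6.12. Cldn18 lies near 12.36 in FC1199-OVA and near 3.71 in FC1242-OVA, the widest gap of the genes plotted.

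Beyond Cldn18, the lines differed in a large part of the transcriptome. At an adjusted p under 0.05, 7477 genes (41.7%) were called, 3906 of them higher in FC1242-OVA and 3571 higher in FC1199-OVA. Among these, 1272 differed at least 2-fold, 683 higher in FC1242-OVA and 589 higher in FC1199-OVA. At least 4-fold differences were called for 291 genes and at least 16-fold differences for 33. The 3 values of each line did not overlap in 51.8% of genes, where chance gives 10%.

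The gene most elevated in FC1242-OVA was Sox2, a transcription factor of pluripotent cells and foregut epithelium, which measured 10.25 ± 0.10 there against 2.20 ± 0.17 in FC1199-OVA, 265-fold higher (adjusted p = 1.19e-08). Mdfic, an inhibitor of MyoD-family transcription factors, was 134-fold higher, and Cdh13, encoding the GPI-anchored T-cadherin, 44.2-fold higher. The other genes of the top 10 in this direction were Krt76, encoding an epithelial keratin (difference 5.42), Pcdh7, a protocadherin gene (4.89), Mfap3l (4.77), Prss12, which encodes the serine protease neurotrypsin (4.46), Kdm5d (4.36), Eif2s3y (4.26) and Bhlhb9 (4.16). Kdm5d and Eif2s3y are Y-linked. Their other probe sets on the array were not called.

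After Cldn18, the genes most elevated in FC1199-OVA were Apob, encoding the structural protein of low-density lipoprotein, at 9.58 ± 0.11 against 3.32 ± 0.19 (76.2-fold, adjusted p = 2.33e-08), and Nexmif (difference −5.50). They were followed by Tns4, encoding a focal adhesion protein (−5.39), AI467606 (−5.21), Diras2, encoding a Ras-family GTPase (−5.08), and Cfap69, a cilia and flagella gene (−5.05). Rnf125, an E3 ubiquitin ligase gene (−4.84), Pygl, encoding liver glycogen phosphorylase (−4.76), and Gsta3, a glutathione transferase gene (−4.45), completed the list. By the naming rule, and so not as a separate result, each of these 10 genes had 3 higher values in FC1199-OVA than in any FC1242-OVA array.

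**Figure D2:**
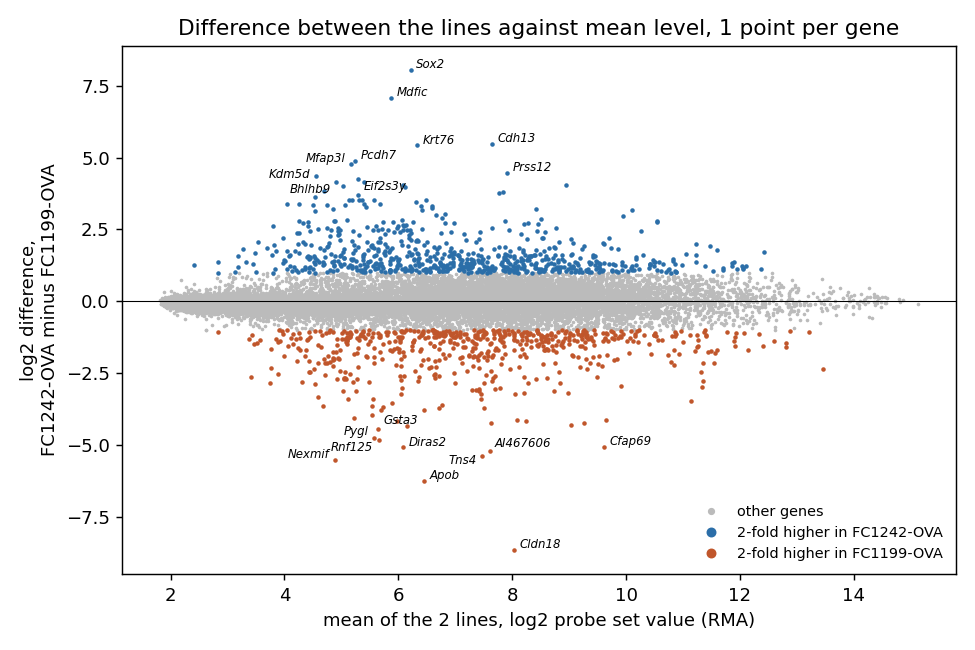
Log2 difference between the lines (vertical axis, FC1242-OVA minus FC1199-OVA) against the mean log2 value of the 2 lines (horizontal axis), 1 point per gene, with the 683 genes called at least 2-fold higher in FC1242-OVA in blue, the 589 higher in FC1199-OVA in orange and the other genes in grey. The labelled genes are the top 10 in each direction by the naming rule, with Cldn18 at −8.65 and Sox2 at 8.05.

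Claudin and tight junction genes differed in both directions. Of 27 measured, Cldn18 among them, 8 were called higher in FC1199-OVA and 5 higher in FC1242-OVA, with the same numbers when adjusted over the list alone. Cldn23 (7.17 ± 0.03 against 4.92 ± 0.18), Cldn12 (difference −2.12) and Cldn2 (−1.86), whose product forms a cation-selective pore, were higher in FC1199-OVA. The list as a whole did not differ from other genes (camera adjusted p = 0.43; median −0.06, and mean −0.53 with Cldn18 included). Claudin genes alone, grouped by symbol only after results had been seen, leaned more to FC1199-OVA. Of 24, Cldn18 among them, 7 were called higher in FC1199-OVA and 1 higher in FC1242-OVA (median −0.16). That family was not called (camera adjusted p = 0.056 over 317 families; adjusted p = 0.95 with an estimated correlation). Occludin, a transmembrane junction protein, was not called by its brighter probe set, with Ocln at 7.13 ± 0.17 in FC1199-OVA and 7.22 ± 0.13 in FC1242-OVA, while its other probe set was called higher in FC1242-OVA (5.51 ± 0.05 and 5.81 ± 0.11, adjusted p = 0.0287 with every probe set tested on its own). The scaffold gene Tjp1 was called with a difference of 0.24, a call that was lost without FC1199-OVA replicate 2 or 3 and without FC1242-OVA replicate 1 or 3 (adjusted p of 0.0539 to 0.0834; 0.000286 to 0.0834 over all alternatives). Of 22 tetraspanin genes, which encode membrane organisers of a family separate from the claudins, 8 were called higher in FC1242-OVA and 3 higher in FC1199-OVA (8 and 4 adjusted over the list alone). Tspan13 was 18.7-fold higher in FC1199-OVA, and Tspan12 (difference 1.65), Tspan33 (1.41) and Tspan6 (1.23) were higher in FC1242-OVA. The tetraspanin list did not differ from other genes (camera adjusted p = 0.42), and the abundant Cd9 measured 13.45 ± 0.04 and 13.50 ± 0.03.

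Of 20 measured genes listed for MHC class I antigen presentation, which displays peptides such as those of ovalbumin to CD8 T cells, 10 were called higher in FC1199-OVA and 3 higher in FC1242-OVA, also when adjusted over the list alone. The class I heavy chain gene H2-K1 measured 12.03 ± 0.05 in FC1199-OVA and 10.48 ± 0.06 in FC1242-OVA, 2.94-fold higher in FC1199-OVA (adjusted p = 1.76e-06). The class I-like gene H2-M3 differed by −1.92, Sppl2a, encoding an intramembrane protease, by −1.36, and Tap2, a peptide transporter subunit gene, by −1.14. Sppl2a was part of the fixed list, although its protease is known for cleaving the class II invariant chain. It is 1 of the 10 genes called higher in FC1199-OVA. Smaller differences were called for B2m (−0.66), the gene of the light chain, Tapbp (−0.50), encoding tapasin, and H2-D1 (−0.41), although none of the other 4 probe sets of H2-D1 was called. The list was called by camera (median −0.35, adjusted p = 0.042; adjusted p = 0.49 with an estimated correlation). This call was also lost without FC1199-OVA replicate 3 (adjusted p = 0.085) or FC1242-OVA replicate 1 (0.063), with the mean of all probe sets (0.14), with median-centred arrays (0.051) and without dim genes (0.059), within a range of 0.028 to 0.14, while the median lay between −0.39 and −0.24. Of 8 MHC class II presentation genes, 1 was called, Ifi30, a lysosomal thiol reductase gene, with a difference of −0.62. The class II list was not called (camera adjusted p = 0.44), and its call count adjusted over the list alone was also 1.

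Interferon response genes were called higher in FC1199-OVA in 14 of 31 cases and higher in FC1242-OVA in 2, with the same numbers adjusted over the list alone. The largest differences were in Ifih1 (7.04 ± 0.03 against 5.15 ± 0.09, −1.89) and Dhx58 (−1.58), both of which encode cytosolic sensors of viral RNA, the guanylate-binding protein gene Gbp7 (−1.55) and the transcription factor gene Irf7 (−1.37). Dhx58, Gbp7 and Irf7 lay below the median of all genes in both lines. Of the 31 genes, 8 lay above that median in FC1199-OVA and 7 in FC1242-OVA. Stat2, which encodes a transducer of type I interferon signals, differed by −0.56, a call that was lost with the mean of its probe sets (adjusted p = 0.372; 0.00193 to 0.372 over all alternatives). The list was called by camera (median −0.14, mean −0.40, adjusted p = 0.027; adjusted p = 0.33 with an estimated correlation), and the call was lost when dim genes were left out (median −0.27, adjusted p = 0.13; 0.0086 to 0.13 over all alternatives). Its median was −0.26 without FC1199-OVA replicate 2 and −0.22 without FC1242-OVA replicate 2, within −0.27 to −0.1 over all alternatives. Over all genes the median difference was −0.04, and 0.05 once dim genes were left out, so dim genes lay somewhat lower in FC1242-OVA. The interferon genes, most of them dim, were not compared with genes of similar level. Among 26 genes of interferon and TNF receptors and death signalling, 9 were called higher in FC1242-OVA and 7 higher in FC1199-OVA, also adjusted over the list alone. Tnfrsf1b, a TNF receptor gene (−1.31), and Ripk3, a necroptosis kinase gene (−0.72), were higher in FC1199-OVA. Mlkl, which encodes the effector of necroptosis (1.17), and Casp8, encoding the initiator caspase of death receptors (0.76), were higher in FC1242-OVA. This list was not called (camera adjusted p = 0.74, direction up, with a median of 0.09 and a mean of −0.01).

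Several chemokine and cytokine genes were higher in FC1242-OVA. Among 23 T cell and monocyte chemokines and related cytokines, 8 were called higher in FC1242-OVA and 5 higher in FC1199-OVA, also adjusted over the list alone. Cxcl12, a chemoattractant for lymphocytes that signals through Cxcr4, was 11.6-fold higher in FC1242-OVA, the monocyte attractant Ccl2 measured 8.59 ± 0.16 in FC1199-OVA and 10.61 ± 0.14 in FC1242-OVA, and Ccl20 was 3.85-fold higher. Il15, encoding a survival cytokine of CD8 T and NK cells, was 5.54-fold higher in FC1199-OVA but dim in both lines (5.69 ± 0.32 and 3.22 ± 0.16). Of the T cell chemokine genes Cxcl9, Cxcl10 and Ccl5, all below the median of all genes in both lines, Cxcl10 (0.50) and Ccl5 (0.64) were called higher in FC1242-OVA and Cxcl9 was not called (3.57 ± 0.09 and 3.59 ± 0.21). Of 25 genes of neutrophil chemokines and inflammatory cytokines, 10 were called higher in FC1242-OVA and 6 higher in FC1199-OVA, also adjusted over the list alone. The neutrophil attractant Cxcl2 was 8.96-fold higher in FC1242-OVA, the alarmin gene Il33 6.89-fold and Lif 2.57-fold, while Ptges, a prostaglandin E synthase gene, was 8.64-fold higher in FC1199-OVA. Neither list differed from other genes (camera adjusted p = 0.34 and 0.42).

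Adhesion genes for leukocytes differed in both directions. Of 16 genes of T cell adhesion and costimulatory ligands, 4 were called higher in FC1242-OVA and 7 higher in FC1199-OVA, also adjusted over the list alone. Icam1, encoding a ligand of the integrin LFA-1, measured 4.93 ± 0.12 in FC1199-OVA and 8.24 ± 0.09 in FC1242-OVA, 9.9-fold higher, and Vcam1 was 3.8-fold higher. Cd47, encoding a signal against phagocytosis (−0.76), Icosl, a costimulatory ligand gene (−0.64), and Alcam, whose product binds CD6 on T cells (−0.36), were higher in FC1199-OVA. The Icosl call was lost with the mean of its probe sets (adjusted p = 0.0504; 7.54e-05 to 0.0504 over all alternatives). The Alcam call was lost without FC1199-OVA replicate 2 or 3 and without FC1242-OVA replicate 1 or 2 (adjusted p of 0.0776 to 0.0873; 0.00144 to 0.0873 over all alternatives). This list was not called, and its measures differed in sign (median 0, mean 0.19, camera direction down, fry direction up, camera adjusted p = 0.95). Of 26 inhibitory ligands and immune suppression genes, 8 were called higher in FC1242-OVA and 4 higher in FC1199-OVA, also adjusted over the list alone. The adhesion receptor gene Ceacam1 was 8.19-fold higher in FC1199-OVA and the ectonucleotidase gene Nt5e 1.96-fold, while Tgfb2 (1.38) and Vtcn1 (1.03) were higher in FC1242-OVA. Tgfb2 (4.0 ± 0.32 and 5.37 ± 0.21) and Vtcn1, encoding the inhibitory ligand B7-H4 (2.98 ± 0.27 and 4.01 ± 0.01), were dim in both lines. Cd274, encoding PD-L1, differed by 0.34, a call that was lost without FC1199-OVA replicate 1 or 2 and without FC1242-OVA replicate 1 or 3 (adjusted p of 0.0605 to 0.0653; 0.00713 to 0.0653 over all alternatives). The inhibitory list was not called (camera adjusted p = 0.77, direction up, with a median and a mean of −0.04 and fry direction down).

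Both lines had high levels of epithelial keratin transcripts and of vimentin. Krt8 measured 14.41 ± 0.03 and 14.35 ± 0.03, Krt18 14.27 ± 0.01 and 14.24 ± 0.03, and Vim, a mesenchymal intermediate filament gene, 14.25 ± 0.01 and 14.16 ± 0.01, in FC1199-OVA and FC1242-OVA respectively. Cdh1, encoding E-cadherin, measured 11.46 ± 0.02 and 11.59 ± 0.03. None of these 4 genes was called. Of 35 epithelial identity genes, 12 were called higher in FC1199-OVA and 4 higher in FC1242-OVA (12 and 5 adjusted over the list alone). Erbb3, a receptor tyrosine kinase gene (−1.39), Itgb4, a hemidesmosome integrin gene (−1.14), and the transcription factor gene Ehf (−0.98) were higher in FC1199-OVA, and Dsg2, a desmosomal cadherin gene, was higher in FC1242-OVA (1.07). Among 29 mesenchymal identity genes, 9 were called higher in FC1199-OVA and 5 higher in FC1242-OVA, also adjusted over the list alone. The mesenchymal homeobox gene Prrx1 was 10.5-fold higher in FC1242-OVA, where Mmp14 (1.87) and Sparc (1.61) were also higher, while Snai2, encoding the transcriptional repressor Slug, was 5.4-fold higher in FC1199-OVA. Neither list differed from other genes (camera adjusted p = 0.26 and 0.43).

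Markers of gastric and classical pancreatic cancer included the largest differences in both directions, Cldn18 and Sox2. Of 41 measured, 15 were called higher in FC1199-OVA and 9 higher in FC1242-OVA, also adjusted over the list alone. The mucin gene Muc13 was 17.9-fold higher in FC1199-OVA. Gata6, a transcription factor gene of the classical subtype, was not called (8.94 ± 0.10 and 9.13 ± 0.06). Among 24 basal-like markers, 8 were called higher in FC1242-OVA and 4 higher in FC1199-OVA, also adjusted over the list alone. The growth factor gene Ereg (2.07) and the keratin gene Krt15 (1.21) were higher in FC1242-OVA, and Sprr1a, a cornified envelope gene (−2.35), and S100a14 (−1.0) were higher in FC1199-OVA. Of 17 pancreatic ductal and progenitor markers, 7 were called higher in FC1199-OVA and 4 higher in FC1242-OVA, also adjusted over the list alone. Bicc1, which encodes an RNA-binding protein, was 19.5-fold higher in FC1199-OVA and Tm4sf4 11.1-fold, followed by the retinaldehyde dehydrogenase gene Aldh1a3 (−1.12) and the ductal transcription factor gene Sox9 (−1.0). None of these lists was called (camera adjusted p = 0.28, 0.62 and 0.28). For the basal-like list the median was −0.01 and the mean 0.07, with camera direction up.

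Cell cycle genes were mostly higher in FC1242-OVA. Of 37 proliferation genes, 31 were called higher in FC1242-OVA and 1 higher in FC1199-OVA (32 and 1 adjusted over the list alone), with 23 at least 2-fold higher in FC1242-OVA. The cyclin gene Ccne2 was 6.55-fold higher in FC1242-OVA, though dim in both lines (2.97 ± 0.18 and 5.68 ± 0.19), and the replication helicase genes Mcm5 (2.18) and Mcm3 (1.77) were also higher. Mki67, which encodes the proliferation marker Ki-67, measured 8.22 ± 0.06 in FC1199-OVA and 9.88 ± 0.04 in FC1242-OVA, Top2a differed by 1.26 and Cdk1 by 1.19. The 1 gene called in the other direction was Cdk6, encoding a G1 kinase, which was 5.42-fold higher in FC1199-OVA. The list was called by camera (median 1.22, adjusted p = 1e-14; adjusted p = 0.33 with an estimated correlation). Beside these genes, the Actb control for RNA quality, the log2 value of its 3′ probe set minus that of its 5′ probe set, was 0.46 ± 0.05 in FC1199-OVA and 0.29 ± 0.02 in FC1242-OVA (n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). The same control for Gapdh was −0.05 in both lines (exact permutation p = 1). For Pcx it was 1.27 ± 0.14 in FC1199-OVA and 1.57 ± 0.09 in FC1242-OVA (exact permutation p = 0.1), and for Tfrc 2.20 ± 0.42 and 2.59 ± 0.16 (exact permutation p = 0.2), both opposite in sign to Actb.

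**Figure D3:**
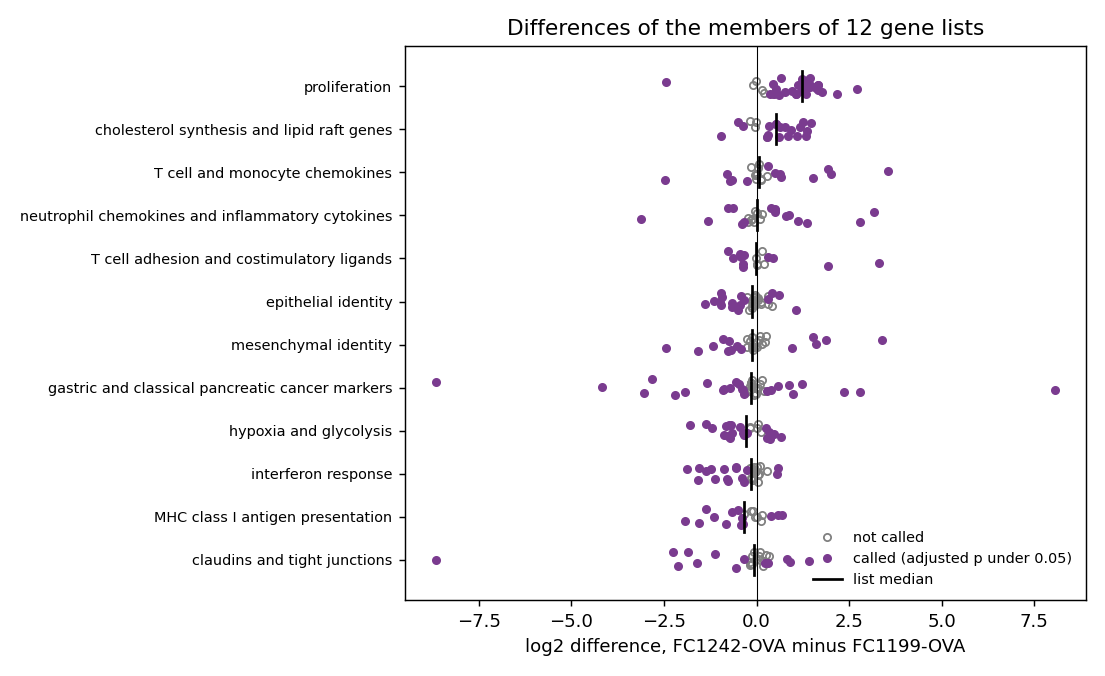
Log2 differences (horizontal axis, FC1242-OVA minus FC1199-OVA) of the members of 12 gene lists (vertical axis), with filled points for genes called at an adjusted p under 0.05, open points for the others and black bars for list medians. The proliferation list has its median at 1.22 and 31 of 37 genes called higher in FC1242-OVA, while the medians of most other lists lie near 0.

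Other growth pathways differed in both directions. Of 21 p53 targets and tumour suppressors, 8 were called higher in FC1242-OVA and 7 higher in FC1199-OVA (9 and 7 adjusted over the list alone). Pmaip1, encoding the pro-apoptotic protein Noxa (−1.83), and Sesn1 (−0.84) were higher in FC1199-OVA, and Plk2 (1.53) and the cell cycle inhibitor gene Cdkn1c (1.05) were higher in FC1242-OVA. Of 27 TGF-beta and BMP pathway genes, 12 were called higher in FC1199-OVA and 8 higher in FC1242-OVA (12 and 10 adjusted over the list alone). The matrix protein gene Tgfbi was 10.4-fold higher in FC1242-OVA and the co-receptor gene Tgfbr3 3.46-fold, while Ltbp2 (−2.50) and the ligand gene Bmp2 (−2.14) were higher in FC1199-OVA. Among 28 WNT pathway genes, 9 were called higher in FC1242-OVA and 4 higher in FC1199-OVA, also adjusted over the list alone. The non-canonical ligand gene Wnt5a was 10.3-fold and the antagonist gene Dkk2 6.99-fold higher in FC1242-OVA, and the receptor gene Fzd1 (−2.17) and Wnt4 (−1.82) were higher in FC1199-OVA. None of these lists was called (camera adjusted p = 0.95, 0.42 and 0.42). For the p53 list the median was 0.03 and the mean −0.02, with camera direction down.

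Cholesterol synthesis genes were mostly higher in FC1242-OVA. In the list of cholesterol synthesis and lipid raft genes, 16 of 23 were called higher in FC1242-OVA and 3 higher in FC1199-OVA (17 and 3 adjusted over the list alone). Msmo1 (10.09 ± 0.13 against 11.56 ± 0.02), Fdft1 (1.37), Nsdhl (1.32) and Sqle (2.38-fold), all enzymes of the pathway, were higher in FC1242-OVA, as was Hmgcs1 (1.10), which acts before HMG-CoA reductase. Cyp51, encoding another enzyme of the pathway, was higher in FC1199-OVA (−0.96). The list was called by camera (median 0.53, adjusted p = 0.00046; adjusted p = 0.49 with an estimated correlation), and the call was lost when dim genes were left out, with the median still at 0.53 (adjusted p = 0.055; 0.00031 to 0.055 over all alternatives). Of 26 hypoxia and glycolysis genes, 14 were called higher in FC1199-OVA and 7 higher in FC1242-OVA, also adjusted over the list alone. The hypoxia-responsive gene Ndrg1 (−1.78), the glycolytic regulator gene Pfkfb3 (−1.37), Aldoc (−1.21) and Eno2 (−0.88) were higher in FC1199-OVA. The hypoxia list was not called (camera adjusted p = 0.066, median −0.29) except without FC1199-OVA replicate 1 (0.037; 0.037 to 0.16 over all alternatives) and, at a value that rounds to 0.05, without FC1242-OVA replicate 3. Among 38 extracellular matrix and integrin genes, 13 were called higher in FC1199-OVA and 12 higher in FC1242-OVA (13 and 13 adjusted over the list alone). The basement membrane gene Nid1 was 7.87-fold, the integrin gene Itgb3 3.88-fold and the plasminogen activator gene Plat 2.99-fold higher in FC1199-OVA, and the collagenase gene Mmp13 was 3.35-fold higher in FC1242-OVA. This list was not called (camera adjusted p = 0.95, direction down, with a median of 0.1 and a mean of −0.1).

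Markers of other cell types that the cultures could hold were mostly low in both lines. Of 13 fibroblast markers, 0 lay above the median of all genes in either line and 1 was called, Des (−0.39), but 0 when adjusted over the list alone (limma; 3 at an unadjusted p under 0.05). Dcn, an abundant fibroblast transcript, measured 4.0 ± 0.06 and 3.93 ± 0.11. The Des call was lost without FC1242-OVA replicate 2 (adjusted p = 0.055) or 3 (0.0681), within a range of 0.0102 to 0.0681. Among 15 leukocyte markers, 2 were called, both higher in FC1199-OVA and both also adjusted over the list alone. They were Mrc1, a macrophage mannose receptor gene (10.34 ± 0.15 against 8.06 ± 0.12), and the lysosomal gene Cd68 (−1.08), while the pan-leukocyte gene Ptprc was at 2.73 ± 0.16 and 2.50 ± 0.10. Of 12 endothelial markers, 2 were called higher in FC1199-OVA, Egfl7 (−0.95) and Emcn (−0.35), with 1 adjusted over the list alone. The Emcn call was lost with quantile normalization (adjusted p = 0.096) and in 5 of the 6 fits that left out an array, all except the one without FC1242-OVA replicate 3, within a range of 0.00454 to 0.12. Among 13 acinar and endocrine markers, Cela1 was called higher in FC1242-OVA (0.83) and Prss2 higher in FC1199-OVA (−0.47), both also adjusted over the list alone. The Prss2 call was lost with the mean of its probe sets (adjusted p = 0.173) and without FC1242-OVA replicate 3 (0.0512), within a range of 0.00112 to 0.173. None of these marker lists was called (camera adjusted p = 0.7, 0.42, 0.42 and 0.74).

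Of 4 sex-linked genes, the Y-linked Kdm5d, Eif2s3y and Uty (2.35 ± 0.13 against 5.75 ± 0.12) were called higher in FC1242-OVA, also adjusted over the list alone. Xist, expressed from the inactive X chromosome of female cells, was dim in both lines (2.30 ± 0.06 and 2.22 ± 0.13). The list was called by camera (median 3.83, adjusted p = 0.016; adjusted p = 0.33 with an estimated correlation). The call was lost when dim genes were left out (median 4.31, adjusted p = 0.094; 0.0057 to 0.094 over all alternatives), and the median was 1.44 with the mean of all probe sets. The 3 called genes share the Y chromosome, so their calls, and with them the call of the list, do not rest on independent genes.

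Camera called 5 of the 28 lists, and with an estimated correlation it called 0, although 3 lists had an unadjusted p under 0.05. Fry, which asks only whether a list's genes move on balance one way and does not compare them with other genes, called 21. Each comparison is between 1 line and 1 other line, so a difference belongs to these lines and cannot be assigned to Cldn18 or to any other single feature in which they differ.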

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

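The alternatives below were chosen before the data were examined. The number of genes called was 6680 to 7935 under the alternatives that keep 1 value per gene and all arrays, and 6306 to 7081 without 1 array, against 7477. It was 12042 when every probe set was tested on its own, with 2167 at least 2-fold, which follows from testing 34248 probe sets in place of 17931 genes. Treat, which tests whether a difference exceeds 2-fold, called 619 genes against 1272 that were called and measured at least 2-fold. Under the other alternatives the 2-fold count lay between 1010 and 1290, and without 1 array between 1265 and 1309. The share of calls that were higher in FC1242-OVA was 52.2%, and 47.5% after median centring, and no scaling moved the median of all genes by 0.1. Cldn18 differed by −7.45 to −8.78 and was called under each of 14 alternatives. Camera called 5 lists, 4 to 6 without 1 array, and 1, the proliferation list, when dim genes were left out. That filter leaves 9389 genes as the background and fewer members of many lists, though all 23 of the cholesterol list. With an estimated correlation camera called 0 lists, and fry, which has no comparison with other genes, called 21. The proliferation list was called under each of the 13 alternatives that repeat camera with its preset correlation, with medians from 0.87 to 1.24. Same-numbered arrays of the lines had deviations from their line's mean that correlated at 0.095, −0.043 and 0.051 across genes, not all over 0.1, and FC1199-OVA replicate 2 correlated best with FC1242-OVA replicate 3 (0.101), so the numbers were not taken to pair the arrays. With the replicate number as a replicate block, 7230 genes were called, of which 6941 were also called without it, 1272 at least 2-fold, and 4 lists, without MHC class I presentation (adjusted p = 0.074). Besides Cldn18, 160 genes were followed, by the naming rule or chosen later, with 2207 values under the alternatives. Of these, 2163 kept their direction and their side of the threshold, 25 lost their call, 8 gained one and 11, of 5 genes, changed sign, none of them called in either fit. They were Cxcl9 with the mean of probe sets (−0.062), array weights (−0.017) and median centring (−0.014) and without 1 array (−0.102 to 0.082), Dcn with quantile normalization (0.004), Cldn1 with quantile normalization (0.037) and without 1 array (−0.079 to 0.001), Fcer1g without 1 array (−0.167 to 0.024) and Laptm5 with the mean of probe sets (−0.18). The genes that lost a call were Icosl, Des, Emcn, Prss2, Alcam, Cd274, Stat2 and Tjp1, the last also with the block (0.0537), and those that gained one were Cdh1, Vim, Gata6, Ptprc, Laptm5 and Coro1a, the last with the block and higher in FC1199-OVA (−0.256, adjusted p = 0.0398); the cause was not tested. Signal over background limits the values near the floor of the arrays, where folds such as those of Cldn18 and Sox2 are compressed.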

Other observations

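The explanations weighed for the proliferation and MHC class I lists and the grouping of genes by symbol were tested only after those results had been seen. Grouped by the letters that start their symbols, genes formed 317 families of at least 8 members, and camera called 2 of them. The Mcm family, mostly subunits and partners of the replication helicase, had 9 of 10 members called higher in FC1242-OVA and 0 higher in FC1199-OVA (median 1.07, adjusted p = 0.00014; adjusted p = 0.95 with an estimated correlation). The proliferation list also holds Mcm2 to Mcm7, so the calls of this family and of that list are not independent. The Nup family of nuclear pore proteins had 12 of 19 called higher in FC1242-OVA and 1 higher in FC1199-OVA (median 0.34, adjusted p = 0.029; adjusted p = 0.95 with an estimated correlation), with Nup93 at 0.79.

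The following families were not called by camera and were picked for their counts after these had been seen, while others had balanced counts, such as the keratins with 7 of 48 called higher in each line. Among proteasome regulatory subunits (Psmd), 10 of 14 were called higher in FC1242-OVA and 2 higher in FC1199-OVA (camera adjusted p = 0.056), with Psmd7 at 1.30. Of 10 mucin genes, 7 were called higher in FC1199-OVA and 0 higher in FC1242-OVA (adjusted p = 0.088). The small proline-rich genes of the cornified envelope had 5 of 9 called higher in FC1199-OVA and 0 higher in FC1242-OVA (adjusted p = 0.056), led by Sprr2h, which measured 11.71 ± 0.08 in FC1199-OVA and 7.59 ± 0.04 in FC1242-OVA (n = 3 each). Of 73 cytochrome P450 genes, 19 were called higher in FC1199-OVA and 1 higher in FC1242-OVA (adjusted p = 0.088), among them Cyp4b1, 9.38-fold higher in FC1199-OVA. Myosin genes with symbols that start with Myo had 11 of 23 called higher in FC1199-OVA and 1 higher in FC1242-OVA (adjusted p = 0.056), with Myo7b, a myosin of the brush border, 8.43-fold higher in FC1199-OVA. Myosin heavy chain genes (Myh) had 5 of 10 called higher in FC1199-OVA and 0 higher in FC1242-OVA (adjusted p = 0.35). For light chain genes (Myl) it was 1 of 11 and 0 (adjusted p = 0.71).

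Neighbouring genes tended to differ in the same direction. With 9383 expressed genes in chromosome order (GRCm38.p6, used only for the order), the differences of genes 10 places apart correlated at 0.133 across gene pairs that share no symbol stem, against at most 0.036 in 1000 shuffled orders (permutation p = 0.001, the smallest they can give), which argues against paralogs or shared probes as the cause. For the candidate explanation of a copy number difference between the lines, 16 of 364 windows of 25 genes had a median more than 0.49 away from 0.05, the median of all placed genes, a distance that 95% of shuffled orders stay within, 10 of them higher in FC1199-OVA and 6 higher in FC1242-OVA. Regional regulation of chromatin and segments of another mouse strain may give such windows too and were not tested. The tendency reached beyond these windows, with a correlation of 0.096 at 50 places, and 0.1 without the most extreme window and the genes beside it. Long runs of windows shared 1 sign, as from 4930527J03Rik to Uap1 (medians of 0.23 to 0.79) and from Crem to Haus1 (−0.48 to −0.25). The run from Crem to Haus1 took in all windows of its chromosome. So did those from Abhd6 to Mycbp2 (0.22 to 0.65) and from Vamp7 to Phka2 (0.16 to 0.5). Whether regional regulation or strain segments could reach over a whole chromosome was not tested. Other stretches held both signs. The most extreme window, from Cdk6 to Dmtf1, had 25 of 25 expressed genes called higher in FC1199-OVA (median −1.89), among them Cldn12, Fzd1, Cyp51, Cfap69, Steap1 (−1.87), Steap2 (−2.15), Abcb1a (−1.38), Rundc3b (−2.63), Tmem243 (−2.47) and Dbf4 (−0.72), so that the 1 proliferation gene called higher in FC1199-OVA, Cdk6, and 1 of the 3 such genes of the cholesterol list, Cyp51, lie there, and the next expressed genes went both ways, with Sema3a at 0.56 and Sema3e at −1.92. A gene counted as expressed if its mean in the higher line lay above the median of all genes. Of 6 dim genes between the ends of this window, 4 were lower in FC1242-OVA and 0 were called higher in FC1199-OVA (median −0.1). The 10 expressed genes on each side of Cldn18 had a median of 0.25 (SE 0.16), with 13 of 20 higher in FC1242-OVA, which argues against a regional copy number difference as the cause of its −8.65. That SE takes neighbours as independent, although their differences correlate. A loss confined to Cldn18 and a few neighbours would hardly move this median and stays open.

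A scaling of the arrays would move genes of the same level alike, but the proliferation genes exceeded the median of the 200 other genes nearest to each in mean level by a median of 1.15 (SE 0.12, from a bootstrap over genes), and those medians lay between −0.13 and 0.14, which argues against scaling as the source of the higher list in FC1242-OVA. That SE measures the spread over genes, taken as independent, and not over samples. A difference in RNA quality cannot be told apart from the difference between lines, because the Actb 3′ minus 5′ value differed by −0.166 with the line, at an exact permutation p of 0.1 that 3 against 3 cannot go below. The Pcx and Tfrc controls differed the other way, by 0.306 and 0.383 (exact permutation p = 0.1 and 0.2). A faster cycle of FC1242-OVA, or a difference in density at harvest, may give the same pattern and was not tested.

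For the MHC class I list, probe sets shared between similar H2 genes could make 1 difference look like several. The 17 members outside the H2 family, Sppl2a among them, had a median of −0.15 (SE 0.17, from a bootstrap over genes), with 7 called higher in FC1199-OVA and 3 higher in FC1242-OVA, which leaves open how far the list extends beyond H2 genes, and the explanation cannot be told apart from a true difference. Leukocytes in the FC1199-OVA cultures would bring their abundant transcripts, but of Ptprc, Lyz2, Tyrobp, Fcer1g, Laptm5 and Coro1a, 0 were called higher in FC1199-OVA (limma; 1, Ptprc, at an unadjusted p under 0.05) and 1, Laptm5, lay above the median of all genes, with levels from 2.73 to 6.31. Of their 13 probe sets, 12 lay below that median, and these levels argue against leukocytes as the source of the list's difference, although another Laptm5 probe set was called higher in FC1199-OVA (−0.44, adjusted p = 0.0299 with every probe set tested on its own), Mrc1 and Cd68 were called higher there too, and so was the dim Ptprc without FC1199-OVA replicate 2 (adjusted p = 0.0457) or after median centring (0.0463; 0.0457 to 0.484 over all alternatives). A difference between the lines in the regulation of these genes stays among the open explanations, as untested.

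The 6 arrays can be split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. The real split called 7477 genes, 1272 of them at least 2-fold, and the highest other split called 0 and 0 with limma, where 150 to 386 genes had an unadjusted p under 0.05. Every other split puts arrays of both lines in each group. The difference between the lines then enters the spread, so that calls could hardly arise, and these counts do not measure what chance gives. For each count, 1 of the 10 splits, the real one, gave a result as large.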
